A study of Mus musculus with 76 samples.

How the data were processed

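Methylated DNA was measured in mouse embryonic fibroblasts with a normal Lsh gene (Lsh+/+, called WT here) and in fibroblasts lacking Lsh (Lsh−/−, called KO here). Sonicated DNA was pulled down with an antibody against methylated cytidine (MeDIP) and hybridised beside untreated input DNA to NimbleGen tiling arrays of mouse build MM8 with probes of 50 bases. The labels describe the DNA as pooled before hybridisation, so each genotype was represented by 1 preparation spread over 38 arrays, 76 in all, and each array of a genotype covered another part of the genome. A probe therefore had 1 WT value and 1 KO value, and no test per probe or per region was possible.

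The deposited scanner values were probe intensities on a linear scale, extracted with NimbleScan 2.3 per the labels, with the Cy3 channel holding the MeDIP DNA and the Cy5 channel the input per the labels' dye assignment. The authors also deposited a −log10 P for every probe from a one-sided Kolmogorov-Smirnov test of normalised log2 ratios against the rest of the array, per the labels' protocols, and the type field of the deposited files names a window of 750 bp. The −log10 P values of the whole-series tables were equal to those of the arrays' files on all 385496 tiling probes of a full array. The deposited −log10 P correlated with the log2 ratio of MeDIP over input computed here on every array, with r across probes from 0.281 to 0.541 on WT arrays and from 0.404 to 0.526 on KO arrays, which fixed the direction of the ratio as MeDIP over input.

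From the intensities, log2(MeDIP/input) was computed per probe without background subtraction and centred on the median of the tiling probes of its array. Array sets with at least 100000 tiling probes on both arrays were compared, which left 36 sets and 13877856 probes on the 19 autosomes. Array set 37 held 15416 tiling probes and array set 38 held 3840 random-sequence control probes and no tiling probe, so both were left out. Sequence not placed on a chromosome position stayed in the measures of whole arrays and out of windows and bins. The X and Y chromosomes were not analysed here.

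An enriched probe had a deposited −log10 P of at least 2. Enriched regions were runs of such probes joined over up to 500 bp, with at least 2 probes, and a region was shared if it overlapped a region of the other genotype by at least 1 bp. Windows of 100 kb needed at least 100 probes and bins of 10 kb at least 30. A window was counted as different when its odd-numbered and its even-numbered probes both differed in the same direction by at least 0.2 (100 kb) or 0.5 (10 kb) on the log2 scale. The level of a bin was the mean of WT and KO, split in 5 equal groups per array. Probes next to a tiling gap lay within 500 bp of a stretch of at least 1000 bp without probes. Regions to name were fixed before the data were examined, as the 3 lowest and 3 highest 100-kb windows and the 5 lowest and 5 highest 10-kb bins among those counted, after joining neighbours. The longest joined stretches and the windows kept after local centring were chosen for description after their values were seen.

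Measures of whole arrays were compared with a 2-sided sign-flip permutation test of the KO minus WT difference over the array sets, with 100000 resamples, so that 1e-05 is the smallest p these permutations can give. Benjamini-Hochberg adjustment covered the 7 tested results. These p-values compare the 2 DNA preparations beyond the spread between arrays, not the genotypes, because the cultures behind the preparations were not replicated. WT and KO arrays were paired by array set, since arrays of one set number carry the same probes. Across the 36 sets the WT and KO values of the tested measures correlated between −0.277 for the median absolute deviation and 0.262 for the enriched share, so the pairing rests on the shared probes and not on a shared deviation of the values.

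Signal over background differed between the arrays. The median input signal of the tiling probes was 1.02 to 7.72 times that of the random-sequence control probes on the WT arrays (median 4.21) and 1.90 to 8.99 times on the KO arrays (median 4.55). Arrays under 2 times are called dim, which held for 8 WT arrays and 1 KO array. The 27 array sets with 2 bright arrays were analysed apart as an alternative chosen after seeing the data.

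Other settings tried were normexp background correction (limma, offset 50), scaling each array's median absolute deviation to the mean of its set, loess of the ratio on mean log intensity within each array (span 0.3), medians in place of means, other thresholds, overlaps, probe minimums and gap sizes, leaving out the dimmest 10% of the probes, leaving out each array set in turn, and a permutation without the pairing. Loess followed by subtracting the median of each probe's 1-Mb window (local centring) was added after seeing the data. Local centring removes differences that span a whole 1-Mb window by construction, so it cannot test them. Tools were R 4.3.3 with data.table (version 1.17.8) and limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

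The window, region and test code was tested on simulated data made on 1 array set of 385496 probes. All 100 bins of 10 kb shifted by 0.75 and all 20 windows of 100 kb shifted by 0.3 were recovered. Of the bins without a planted 10-kb shift 0 of 5458 were counted, and of the windows without a planted 100-kb shift 10 of 600. Both sizes of shift were planted on the same KO values, so neither group was free of shifts. The simulated noise was independent between probes, so these counts are not false-call rates for the real arrays. Of 100 sign-flip tests without an effect, 5 fell under 0.05.

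Promoters, gene lists and the Lsh locus (gene symbol Hells) had been planned, but a gene annotation of build MM8 was not used here, so regions are given by coordinates of MM8 without gene names, and these comparisons were not analysed here. The log2 ratio scaled by the authors was not used here. The histone methylation and gene expression data of the study were not analysed here.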

Results

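Cytosine methylation was mapped by MeDIP and whole-genome tiling arrays in WT and KO mouse embryonic fibroblasts, to ask how the methylation pattern depends on Lsh. Lsh, also called Hells, is a chromatin remodelling protein of the SNF2 family, and its loss is known to lower DNA methylation in mouse cells. The comparison covered 36 array sets, each with 1 WT and 1 KO array, and 13877856 probes. A value below is log2(MeDIP/input) centred on its array, so a level is relative to the rest of the same array and a shift of the whole genome cannot be seen. There were no replicate cultures, and errors are standard deviations (SD) over array sets.

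KO arrays had a larger share of their probes in enriched stretches than WT arrays. The share was 3.28% ± 1.41 (SD, n = 36 array sets) in WT and 3.99% ± 0.807 in KO, a difference of 0.718 percentage points ± 1.43, and it was higher in KO in 25 of 36 sets. The 2-sided sign-flip permutation test gave p = 0.00447 (adjusted p = 0.0156). Without the dimmest 10% of the probes the difference was 0.371 points (p = 0.0308). In the 27 sets with 2 bright arrays it was 0.379 points with p = 0.123, and in the 8 sets with a dim WT array it was 2.03 points, higher in KO in all 8. The difference between these 2 kinds of set had p = 0.00233 in a permutation test.

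**Figure D1:**
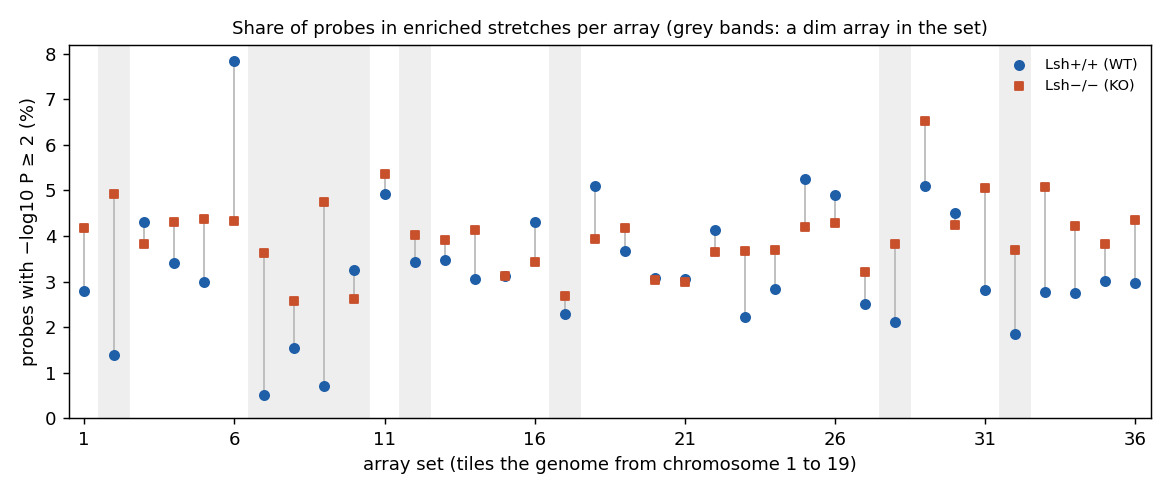
Percentage of probes with a deposited −log10 P of at least 2 (vertical axis) on each WT array (blue circles) and KO array (orange squares) by array set along the genome (horizontal axis), with grey bands over the sets that hold a dim array. WT arrays ranged from 0.520% to 7.83% and KO arrays from 2.57% to 6.52%, and the 8 dim WT arrays had a mean of 1.73%.

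Part of the enriched sequence was shared between the WT and KO arrays, and many stretches were called on the arrays of 1 genotype only. No array was repeated, so the overlap that 2 arrays of the same DNA would give is unknown. There were 211957 probes enriched in both, 242669 in WT only and 342279 in KO only. Of the WT-enriched probes, 46.6% were also enriched in KO, and of the KO-enriched probes 38.2% were also enriched in WT. On the 27 sets with 2 bright arrays 198411 probes were enriched in WT only and 237819 in KO only, with 49% of the WT-enriched and 44.5% of the KO-enriched probes shared, against 44258 and 104460 on the 9 sets with a dim array. The number enriched in both was 11.4 times the 18559 that independent calls would give. That number takes no account of neighbouring probes sharing a test window or of probe brightness. Enriched probes were dim on the arrays of the other genotype. Their log2 input signal relative to the array had a median over arrays of −1.47 for WT-enriched probes on KO arrays. For KO-enriched probes on WT arrays it was −1.51. Joined into regions with a median length of 450 bp, WT had 82761 regions, 38605 of them without an overlapping KO region, and KO had 97254, 53209 of them without an overlapping WT region (30557 and 35744 on the bright sets). When a region counted as specific only if the other genotype stayed under a −log10 P of 1, 12347 WT regions (14.9%) and 18747 KO regions (19.3%) remained. No test applied to these counts, since each genotype had 1 preparation.

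Probes called enriched in KO had lower ratios in WT, while probes called enriched in WT had a mean ratio in KO that did not pass a test against WT. At KO-enriched probes the mean log2 ratio was 0.60 ± 0.20 in WT and 0.87 ± 0.14 in KO, higher in KO in 33 of 36 sets (p = 1e-05, the smallest the sign-flip permutations can give). At WT-enriched probes it was 0.75 ± 0.14 in WT and 0.71 ± 0.22 in KO, a difference of −0.04 (p = 0.321). Probes picked for being high in one genotype are lower in the other through noise alone, so neither p-value above is evidence of a difference by itself. Both amounts are equal if nothing else differs, array noise and number of calls included, so the sum of both differences was tested. It was 0.24 ± 0.41, above 0 in 27 of 36 sets, with a sign-flip permutation p of 0.00125 (adjusted p = 0.00875). The sum depended on the processing: it was 0.097 without the dimmest 10% of the probes (p = 0.0354), 0.05 with the widths of the 2 arrays of a set scaled alike (p = 0.453), −0.06 after normexp background correction (p = 0.565) and −0.03 after within-array loess (p = 0.0697). After loess and local centring, a setting added after seeing the data, it was −0.039 and passed in the opposite direction (p = 0.00305).

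The upper tail of the log2 ratios reached farther in KO. The 99th percentile was 1.56 ± 0.25 in WT and 1.74 ± 0.25 in KO, higher in KO in 25 of 36 sets (p = 0.0111, adjusted p = 0.0259, sign-flip permutation test). The 1st percentile was −1.13 ± 0.45 in WT and −1.12 ± 0.20 in KO (p = 0.960), and on the 27 sets with 2 bright arrays it differed by −0.18 (p = 0.0005), while with scaled widths on all sets it differed by 0.11, in the opposite direction (p = 0.0189). The median absolute deviation, a measure of the width of the whole distribution, was 0.37 ± 0.097 in WT and 0.42 ± 0.097 in KO, and the difference of 0.044 ± 0.15 did not pass the test (p = 0.0952, adjusted p = 0.133); on the bright sets it was 0.076 (p = 0.00349), and after normexp on all sets −0.046 (p = 0.137). Normexp background correction turned the difference of the 99th percentile to −0.11 (p = 0.389), scaled widths to −0.030 (p = 0.649), and leaving out the dimmest 10% of the probes left 0.07 (p = 0.204).

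Ordered by their level over 10-kb bins, the parts of the genome with the highest MeDIP ratios had a higher mean in KO, and whether the span of levels differed depended on the array sets used. In the highest of 5 groups the mean was 0.35 ± 0.12 in WT and 0.44 ± 0.095 in KO, with a higher KO value in 26 of 36 sets, and in the lowest group it was −0.21 ± 0.13 in WT and −0.21 ± 0.082 in KO. The span from the lowest to the highest group was 0.56 ± 0.20 in WT and 0.65 ± 0.16 in KO, a difference of 0.090 ± 0.27 that was positive in 22 of 36 sets and did not pass the permutation test (p = 0.0536, adjusted p = 0.0938). On the 27 bright sets the difference was 0.11 with p = 0.0287, over 100-kb windows 0.090 with p = 0.0401, and without the pairing by array set p was 0.0378. It was 0.049 without the dimmest 10% of the probes (p = 0.223), 0.020 with scaled widths (p = 0.313), 0.00062 after loess (p = 0.973) and −0.02 after normexp (p = 0.633).

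Over 100-kb windows the WT and KO arrays differed on most autosomes. Of 23951 windows, 999 (4.17%) were lower in KO and 2494 (10.4%) were higher, so 71.4% of the counted windows were higher. Many lower windows lay on chromosome 8 (219 of 1257 measured) and chromosome 15 (212 of 1006), and many higher windows on chromosome 2 (387 of 1788), chromosome 5 (260 of 1481) and chromosome 13 (215 of 1171), while chromosome 19 had 0 among its 558 windows. Single array sets held many of these. Set 18 on chromosome 8 had 168 lower windows, and set 31, mostly chromosome 15, had 200. Sets 4, 5 and 6 had 157, 101 and 129 higher windows, and set 27 had 109. Sets 2, 7, 9, 12 and 28, all with a dim WT array, had 171, 144, 125, 179 and 193. On the 27 sets with 2 bright arrays, 954 of 17912 windows were lower and 1559 higher, so 62.0% of those counted were higher. The higher windows left after loess, 650 in number, all lay on these 27 sets. After loess chromosome 2 had 132 higher windows, chromosome 5 had 0 and chromosome 13 had 11. Joined with their neighbours, the lower windows formed 207 stretches and the higher ones 586. Differences of odd-numbered and even-numbered probes correlated across windows at r = 0.957, and WT and KO windows correlated at r = 0.762, which was −0.0062 after normexp and −0.360 after loess. Windows are neighbours on shared arrays and are not independent. The split between the directions moved with the processing: 67.5% of the counted windows were higher with medians of the probes, 48.6% after normexp and 44.7% after loess, with 804 lower and 650 higher. Of the windows counted without loess, 605 of the lower and 528 of the higher ones were also counted in the same direction after it, and 40 and 25 after loess and local centring, a setting added after seeing the data. Local centring removes differences that span a whole 1-Mb window by construction, so the last 2 counts do not test such differences.

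**Figure D2:**
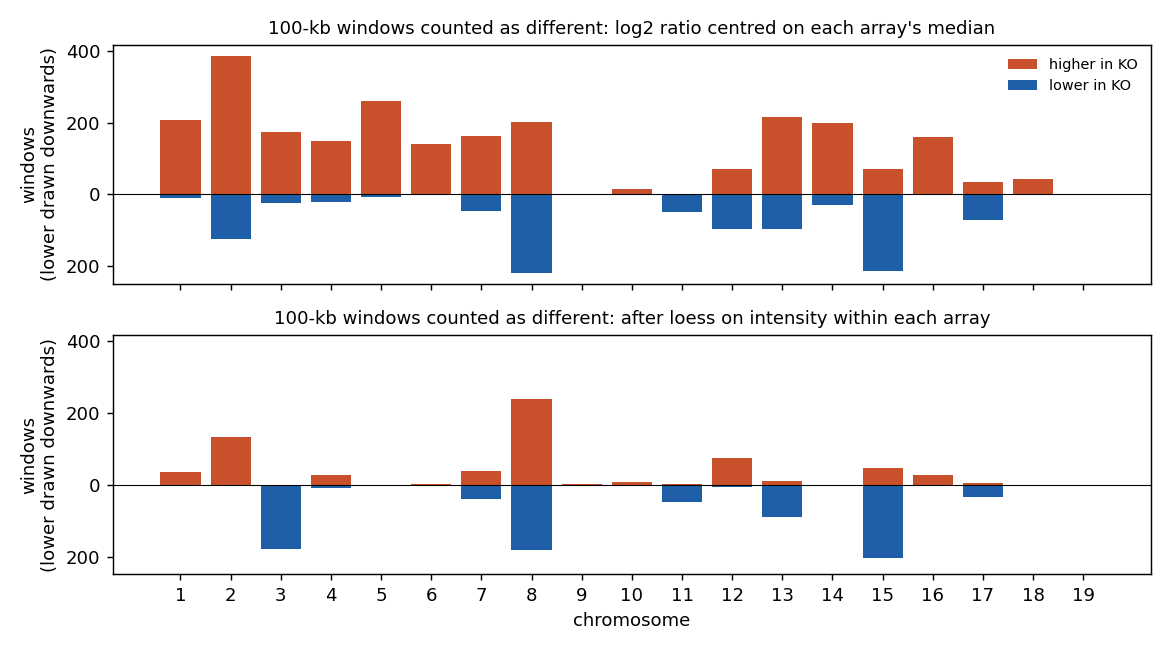
Number of 100-kb windows (vertical axis) counted as higher in KO (orange, upwards) or lower in KO (blue, downwards) on each of the 19 autosomes (horizontal axis), with ratios centred on each array's median (upper panel) and after within-array loess (lower panel). Chromosome 5 had 260 higher windows without loess and 0 with it, whereas chromosome 15 had 212 and 203 lower windows.

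The longest stretch that was lower in KO ran on chromosome 15 from 85400001 to 100500000 (MM8), with 151 windows and 96278 probes, where the mean log2 ratio was 0.20 in WT and −0.15 in KO. The KO minus WT difference was 0.17 in the input channel and −0.14 in the MeDIP channel. The longest stretch that was higher in KO ran on chromosome 8 from 86400001 to 93800000, with 74 windows, and the mean ratio was −0.43 in WT and 0.12 in KO, with a KO minus WT difference of −0.27 in the input and 0.29 in the MeDIP channel. The single lowest windows lay on chromosome 4 from 42400001 to 42500000 (KO minus WT −1.12), on chromosome 17 from 13000001 to 13100000 (−0.90) and on chromosome 13 from 66500001 to 66600000 (−0.89). They had −1.12, −0.78 and −0.82 after loess and −0.42, −0.48 and −0.16 after loess and local centring, and the chromosome 4 window lay on a dim WT array whose input was 1.03 times its control probes. KO minus WT in that window was 2.44 in the input and 1.39 in the MeDIP channel, so its MeDIP signal was higher in KO. It was 0.17 and −0.74 in the chromosome 17 window and −0.14 and −1.08 in the chromosome 13 window. The highest windows lay on chromosome 14 from 5800001 to 5900000 (0.85), on chromosome 11 from 71000001 to 71100000 (0.85) and on chromosome 14 from 18300001 to 18400000 (0.81). Both chromosome 14 windows came from a dim WT array (1.34 times) and had −0.02 and 0.02 after loess, and the chromosome 11 window had 0.81, and 0.79 with local centring.

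**Figure D3:**
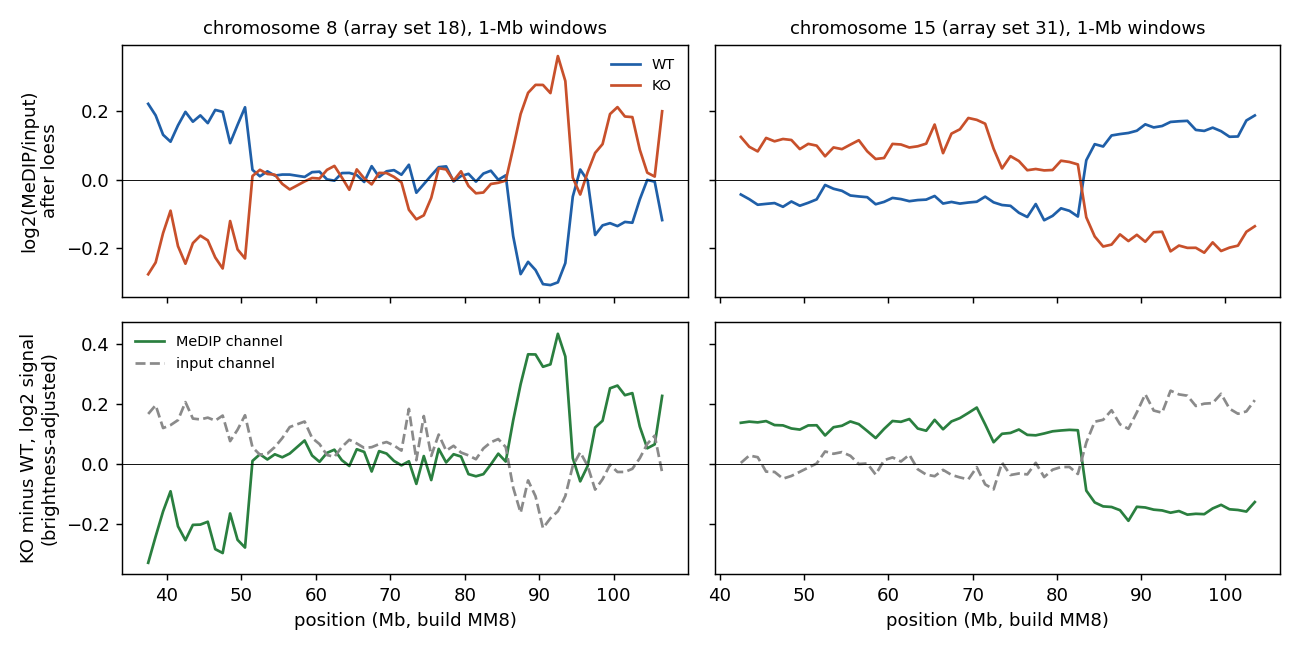
Ratios over 1-Mb windows along chromosome 8 (left, array set 18) and chromosome 15 (right, array set 31), by position in Mb on MM8 (horizontal axes). The upper panels show log2(MeDIP/input) after loess in WT (blue) and KO (orange), the lower panels the KO minus WT difference of the MeDIP channel (green) and of the input channel (grey, dashed), both in log2 units adjusted for brightness; over the longest chromosome 15 stretch the loess ratios were 0.15 in WT and −0.18 in KO.

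At 10-kb resolution the differences were rarer and went both ways. Of 210537 bins, 978 (0.465%) were lower in KO and 1520 (0.722%) were higher, which made 60.8% of the counted bins higher. Chromosome 8 held 288 of the lower and 361 of the higher bins, chromosome 12 held 339 of the higher ones and chromosome 11 held 151 of the lower ones. Single array sets held most of these. Set 18 on chromosome 8 had 288 lower and 357 higher bins. Set 25, which covers parts of chromosomes 11 and 12, had 159 lower and 338 higher bins. After loess chromosome 8 had 104 lower and 372 higher bins, chromosome 12 had 7 higher bins and chromosome 11 had 382 lower ones. Set 18 then had 104 lower and 363 higher bins, and set 25 had 386 lower and 1 higher. The balance stayed at 62.5% higher with medians of the probes (1073 lower, 1788 higher) and was 51.9% on the bright sets (858 and 924) and 49.6% at a threshold of 0.75 (123 and 121). It turned under other treatments: 38.5% of the counted bins were higher after normexp (2593 lower, 1626 higher), 34.3% with scaled widths (1038 and 542) and 38.3% after loess (820 and 508). With local centring 51 of the lower and 26 of the higher bins were still counted in the same direction.

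The lowest bin lay on chromosome 13 from 120610001 to 120620000, with a KO minus WT ratio of −1.83 over 35 probes of a set with a dim WT array. It was followed by chromosome 13 from 66580001 to 66590000 (−1.50), chromosome 13 from 66470001 to 66480000 (−1.46), chromosome 12 from 53850001 to 53860000 (−1.41) and chromosome 4 from 42480001 to 42490000 (−1.39, dim WT array). KO minus WT in the input channel was 1.76, 0.073, 0.066, 0.79 and 3.09 in the order named. In the MeDIP channel it was 0.062, −1.48, −1.45, −0.61 and 1.77, so neither bin with a dim WT array had a lower MeDIP signal in KO. After loess these 5 bins had values from −1.95 to −1.29, and with local centring −1.91, −0.65, −0.63, −1.52 and −0.65 in the order named. With medians of the probes the chromosome 12 bin had −0.82, and the others lay between −1.78 and −1.39. The longest run of lower bins covered chromosome 17 from 13010001 to 13200000, with 19 bins, a mean ratio of 0.18 in WT and −0.68 in KO, and bright arrays in both genotypes, and its difference was −0.41 with local centring. The 5 highest bins all lay on chromosome 14, on array set 28 with its dim WT array. They started at 11930001 (1.36), 4570001 (1.24), 18360001 (1.20), 6260001 (1.18) and 5670001 (1.18), and after loess their values lay between −0.045 and 0.20. The longest run of higher bins, on chromosome 8 from 92040001 to 92370000 with 33 bins, had −0.49 in WT and 0.21 in KO and a difference of 0.70 after loess and 0.021 with local centring. This run lay inside the longest higher stretch of 100-kb windows, so local centring removed its difference by construction.

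Tiling arrays leave out sequence, much of it repeats, that a probe cannot tell apart, so probes at the edge of a tiling gap lie nearest to it. These probes had higher ratios than the other probes in both genotypes, by 0.11 ± 0.032 in WT and 0.12 ± 0.041 in KO. The difference between the genotypes was 0.0092 ± 0.051, positive in 20 of 36 sets, and did not pass the sign-flip permutation test (p = 0.284, adjusted p = 0.332). With loess and local centring, a setting added after seeing the data, it was −0.0075 (p = 0.00381), and 5 of the planned settings gave values below 0 that did not pass.

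**Figure D4:**
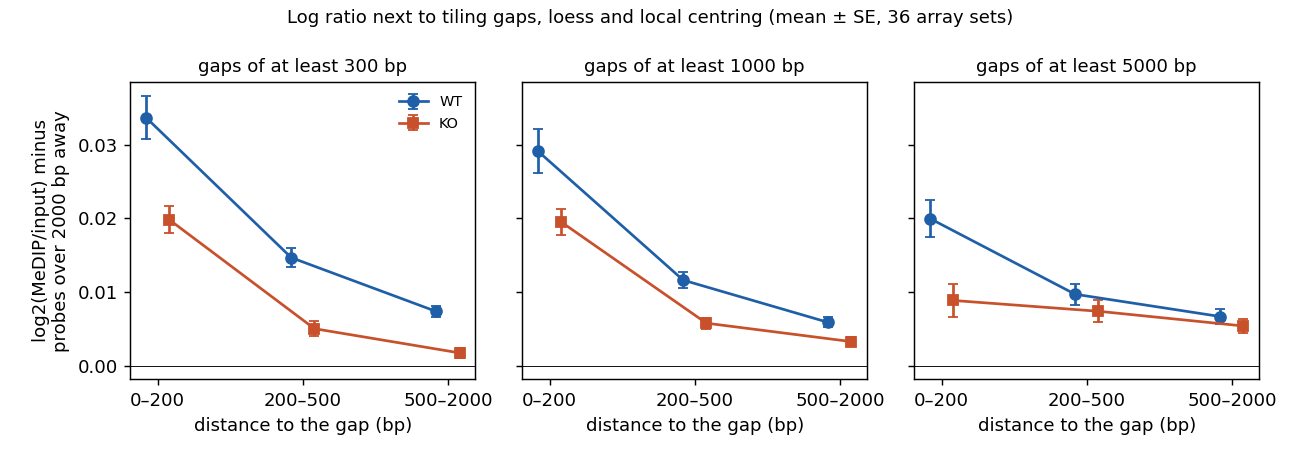
Mean log2(MeDIP/input) after loess and local centring, relative to probes over 2000 bp from a gap (vertical axis), by distance from tiling gaps of at least 300, 1000 and 5000 bp (panels), for WT (blue) and KO (orange), with standard errors over 36 array sets. Within 200 bp of gaps of at least 300 bp the mean was 0.034 in WT and 0.020 in KO.

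The input channel, which holds no immunoprecipitated DNA, also differed between the WT and KO arrays along the chromosomes. With 1 array per genotype in each set, differences between arrays and between genotypes cannot be told apart. Over 2423 windows of 1 Mb the SD of the KO minus WT input signal within a set had a median of 0.084 over the 36 sets and ranged from 0.032 to 0.52. Odd-numbered and even-numbered probes gave nearly the same differences, with r across windows from 0.893 to 0.999. In the 27 sets with 2 bright arrays the median SD was 0.071, and in the 9 sets with a dim array it was 0.28. Adjusted for probe brightness, the median was 0.073 over all sets (highest 0.29), 0.060 on the bright sets and 0.13 on the sets with a dim array.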

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

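The tests on the opposite steps of WT and KO, on noise shared with the input signal and every choice of array sets by their correlations, and the choice of 27 and of 35 sets for the range of the KO ratios, were made only after the results were seen. Below a correlation of −0.3, a limit set after the values were seen, lay 6 array sets on which the KO minus WT differences of the input and of the MeDIP signal, adjusted for probe brightness, ran against each other over 1-Mb windows. This stood out because the input holds no immunoprecipitated DNA and the 2 signals ran together on most other sets, with a seventh set, 25, at −0.192. The correlations across windows were −0.735 on array set 1, −0.838 on set 18, −0.453 on set 19, −0.473 on set 23, −0.894 on set 31 and −0.785 on set 33, against a median of 0.558 over all 36 sets. The 6 sets all had 2 bright arrays.

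Sets 18 and 31 hold the longest stretches on chromosomes 8 and 15, where WT and KO ratios after loess moved in steps of opposite sign, and loess left at least 0.956 of their difference, which argues against probe brightness there. At the 18 chromosome boundaries within arrays brightness is not excluded, because WT and KO steps correlated at −0.539 after loess (permutation p = 0.0273, adjusted p = 0.0410 over 3 relations; rho = −0.432, p = 0.0748) and at −0.424 without the 2 farthest (p = 0.106). On the 6 sets where WT and KO correlated below −0.8 after loess, the median correlation of the input and MeDIP differences was −0.760, which MeDIP and input DNA from cell lines of different copy number could give, but the limit was set after all correlations had been seen, set 17 among them had 0.482, and the limit of −0.7 gave −0.453 over 9 sets. This stays open. At the 18 boundaries, which were not chosen by it, the same correlation was −0.085 (permutation p = 0.745, rho = −0.129 with p = 0.608, r = −0.088 without the 2 farthest), and 9 had opposite signs. Most of these boundaries lay outside the 6 sets, so the correlation cannot decide for them. Of the 6, sets 17, 25, 31 and 33 held a boundary, with opposite input and MeDIP steps (0.10 and −0.084, −0.13 and 0.48, −0.21 and 0.13, 0.14 and −0.14). These sets were chosen by opposite WT and KO ratios, so their steps do not decide it either. A methylation difference over megabases stays open too, since the SD of the input differences was 0.821 times that of MeDIP but 1.20 times on the other 30 sets.

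Enriched stretches of both genotypes lay on probes that were dim on the other genotype's arrays. The median over arrays of their log2 input signal there, relative to the array's median, was −1.47 for WT-enriched and −1.51 for KO-enriched probes. Noise shared by a ratio and its own input signal is argued against, because the ratio correlated at −0.690 (median over arrays) with the input signal of the other genotype's array, which shares no such noise. Background signal in both channels may account for much of it, since normexp correction left −0.114, a test set before its result was seen. Normexp can also take true signal for background on arrays of this kind, and a biological reason for enrichment at dim probes was not tested because the design gives no group for it.

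After loess and local centring, ratios next to tiling gaps were lower in KO than in WT, by a setting added after the data had been seen and with the overall difference already known. Within 200 bp of gaps of at least 5000 bp the difference was −0.0113 within 5 groups of equal brightness (sign-flip p = 0.00922, lower in KO in 23 of 36 sets), 1.01 times its size without these groups. Keeping most of its size had been set beforehand as the result without a brightness effect. Loess on brightness came first, so the groups could only remove what loess had left. In another class, from 500 to 2000 bp at gaps of at least 1000 bp, they moved −0.0026 to −0.0021, so probe brightness stays open. A smaller range of all KO ratios is argued against by −0.00978, the distance of KO from the WT value scaled by the ratio of signal SDs (p = 0.00658, 35 sets; the WT array of set 2 gave no signal SD), and by −0.0118 on the 27 sets with 2 bright arrays (p = 0.00598). The values are in line with lower methylation beside the skipped sequence in KO, as a hypothesis from 1 preparation per genotype. Within 200 bp the difference did not grow steadily with the gap (−0.0139, −0.0096 and −0.0111 at gaps of at least 300, 1000 and 5000 bp), and farther away it passed at 300 and 1000 bp (adjusted p from 4.5e-05 to 0.00229 over 9 classes), though from 500 to 2000 bp at 1000 bp not within the groups of brightness (−0.0021, p = 0.0558), and it did not pass at 5000 bp (p = 0.342 from 200 to 500 bp and 0.323 from 500 to 2000 bp).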

How the results depend on the processing

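The array sets with 2 bright arrays and loess with local centring were chosen only after the results were seen; the other settings were planned. Over the alternatives other than leaving out a set, 51 values kept their direction and call or stayed close, 3 kept their direction and lost the call, 5 kept it and gained one, and 96 moved (64 of them named regions). Another 23 turned their direction, among them values that lost a call and values that passed the test in the opposite direction. Unless a cause is named, the cause was not tested.

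With normexp the KO minus WT difference was −0.046 for the median absolute deviation, −0.11 for the 99th percentile (call lost, p = 0.389), −0.061 for the sum at enriched probes (call lost, p = 0.565), −0.020 by level and −0.0067 at gaps. With scaled widths it was −0.030 for the 99th percentile (call lost, p = 0.649), 0.11 for the 1st percentile (p = 0.0189), 0.046 for the sum and −0.0081 at gaps (p = 0.0599). Loess gave −0.033 for the sum (call lost, p = 0.0697) and −0.0046 at gaps, and loess with local centring gave −0.039 for the sum (p = 0.00305), −0.0035 by level and −0.0075 at gaps (p = 0.00381), the sum and the gaps passing in the opposite direction. The gap difference was −0.0030 at gaps of at least 300 bp and −0.0020 without the dimmest 10% of the probes, where the 99th percentile differed by 0.065, the sum by 0.097 (p = 0.0354) and the enriched share by 0.371 points (p = 0.0308). On bright sets the median absolute deviation differed by 0.076 (p = 0.00349), the 1st percentile by −0.18 (p = 0.0005), the enriched share by 0.379 points and the level span by 0.11 (p = 0.0287). The level span was 0.090 over 100-kb windows (p = 0.0401). Without the pairing by array set as a block, the level span of 0.090 had p = 0.0378 and no other call changed, with 0.044 for the median absolute deviation (p = 0.0579), 0.0045 and 0.18 for the 1st and 99th percentiles (p = 0.958 and 0.00397), 0.718 points for the share (p = 0.00958), 0.24 for the sum (p = 0.00395) and 0.0092 at gaps (p = 0.30). The enriched share kept its call at a −log10 P of 1.3 (1.05 points) and 3 (0.263 points).

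Regions followed their thresholds by construction. At a −log10 P of 1.3 there were 108069 shared and 76629 unshared WT regions and 107245 and 91082 KO regions, at 3 there were 10547 and 13597 against 10554 and 20724, and with at least 4 probes 25918 and 22734 against 25878 and 34235. With an overlap of at least 50% of both regions, 25931 of each genotype were shared, and 12347 WT and 18747 KO regions had no −log10 P of 1 in the other genotype.

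Lower and higher 100-kb windows numbered 1758 and 1663 with normexp, 762 and 1527 with scaled widths, and 804 and 650 with loess. At 0.3 they numbered 517 and 912, and with local centring 53 and 44. On bright sets, which held 17912 of the 23951 windows, they numbered 954 (5.33%) and 1559 (8.70%). Medians of the probes gave 1071 and 2220. The 10-kb bins numbered 2593 and 1626, 1038 and 542, 820 and 508, 123 and 121 at 0.75, 67 and 61, and 858 and 924, with 1073 and 1788 for medians. On chromosome 14, the window at 5800001 had −0.019 with loess and −0.027 with local centring, and the bins had −0.045 and −0.031 at 18360001, −0.023 and −0.0100 at 6260001, and −0.020 and −0.028 at 5670001.

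Leaving out each array set gave 0.031 to 0.053 for the median absolute deviation, which passed without set 8 (p = 0.0448), 12 (0.0476) or 28 (0.0384), and −0.040 to 0.035 for the 1st percentile, below 0 without 9 of the sets with no call. The ranges were 0.15 to 0.20 for the 99th percentile, 0.623 to 0.839 points for the share, 0.21 to 0.27 for the sum, and 0.0053 to 0.012 at gaps, with no call changed. The level span ranged from 0.072 to 0.11 and passed without set 6 (p = 0.0314), 8 (0.0375), 12 (0.0260), 18 (0.0223), 25 (0.0287) or 28 (0.0226). The authors' scaled log2 ratio, promoters, gene lists and the X chromosome were not run, and scaling fixes the median absolute deviation by construction. Signal over background limits the 9 sets with a dim array, where input differences had a median SD of 0.28, or 0.13 when adjusted for probe brightness.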

Other observations

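The 100-kb and 10-kb windows counted after local centring and the comparisons of chromosome starts and of local signal were chosen only after earlier results had been seen. Windows that differ from their own 1-Mb neighbourhood were few, 53 lower and 44 higher at 100 kb and 67 lower and 61 higher at 10 kb. A run on chromosome 13 was lower in KO in 3 neighbouring windows from 67000001 to 67300000, with KO minus WT of −0.71, −0.67 and −0.66 before and −0.51, −0.48 and −0.52 after centring. In that run KO minus WT was −0.69 to −0.88 in the MeDIP channel and −0.17 to 0.066 in the input. Chromosome 11 from 71000001 to 71100000 (0.79 after centring) and chromosome 13 from 12800001 to 13000000 (0.75 and 0.70 in its windows) had higher ratios in KO. There the input held the larger part. KO minus WT was −0.49 in the input and 0.39 in MeDIP on chromosome 11. On chromosome 13 it was −0.48 and −0.37 in the input and 0.18 and 0.20 in MeDIP. Single bins stood apart on chromosome 12 from 53850001 to 53860000 (−1.52), chromosome 17 from 38950001 to 38960000 (−0.98) and chromosome 16 from 93520001 to 93530000 (−0.95), and in the other direction on chromosome 13 from 67480001 to 67490000 (1.03) and from 12860001 to 12870000 (1.03) and chromosome 17 from 35670001 to 35680000 (0.99). The chromosome 12 bin had a KO minus WT difference of 0.79 in the input and −0.61 in MeDIP. Among the bins counted after local centring on bright arrays, input and MeDIP moved in opposite directions in 49 of 56 lower and 39 of 50 higher ones. Among the 100-kb windows they did so in 24 of 49 lower and 30 of 43 higher ones. The choice on MeDIP minus input itself raises these counts.

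WT and KO ratios of the same 10-kb bins correlated at 0.745 across bins as centred on each array, at −0.154 after loess and at 0.20 after loess and local centring. Across 1-kb bins the correlation of WT and KO after loess and local centring had a median of 0.270 over the 36 array sets and ranged from 0.0717 to 0.370. Bins of one array are not independent replicates. The SD of the signal that odd-numbered and even-numbered probes share was 0.070 in WT and 0.069 in KO (p = 0.888, sign-flip permutation test). These values cover all 36 sets, among them set 2, whose WT array gave no signal SD above 0. On the 27 sets with 2 bright arrays the SD was 0.079 in WT against 0.069 in KO (p = 0.0255, same test, lower in KO in 18 sets).

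For 18 chromosomes, loess ratios of probes below 10 Mb, nearest to the mouse centromere, were compared with the chromosome's other probes on that array. They lay higher by a mean of 0.0070 in WT and 0.0047 in KO. The KO minus WT difference of −0.0023 ± 0.093 did not pass the sign-flip permutation test (p = 0.922, higher in KO on 8 of 18), nor did −0.019 without chromosome 1 (p = 0.219).

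Sequence without a position on the build was measured on 8 chromosomes. Its ratio relative to the other probes of the array was lower in KO on 7 of them, or on 5 after loess. Its enriched share was lower in KO on 3 chromosomes, higher on 2 and equal on 3. For chromosome 15, with 272 probes on array set 31, the ratio relative to the other probes was 0.21 in WT and −0.19 in KO. Of these probes 8.46% were enriched in WT against 0% in KO. Set 31 is one of the sets with opposite input and MeDIP differences. After loess the values relative to the other probes were 0.17 and −0.17. The longest placed stretch of chromosome 15 had 0.15 and −0.18, which are means centred on the array and thus a slightly different measure. The enriched share was 9.17% in WT against 0.917% in KO for chromosome 9 (109 probes), 1.10% against 4.55% for chromosome 13 (1912 probes, dim WT array) and 0.827% against 1.23% for chromosome 5 (7497 probes).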
